A study of Homo sapiens with 2 samples.

How the data were processed

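RNA of the human induced pluripotent stem cell line 409B2 was measured on 2 microarrays, 1 of cells before conversion (the pre-conversion array) and 1 of cells after conversion to a state called naïve (the converted array). Per the labels' protocols, total RNA was extracted with Trizol, and 100 ng of it was made into biotinylated single-stranded cDNA with the Affymetrix WT PLUS kit. The culture media, any feeder cells, the conversion method, the scanner settings, the background correction and the normalization are not given in the sources used here.

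The deposited table holds 1 log2 value per probe set and array, and the authors made these values. The log base is not stated. It was taken as 2 from the range of the values, which runs from 1.45 to 19.9, so that a difference of 1 is read as 2-fold. Whether the values were transformed in another way is not stated either. All fold sizes given here rest on that reading. The quartiles of the arrays differ, so the deposited probe set values do not share 1 distribution. A quantile normalization of single probes before they were summarized is not excluded by this. Both arrays have the same minimum (1.45). Scanner files were not used here, so the background and the scaling behind the values could not be redone. Values of a single probe set are compressed near background, which makes the difference of a dim gene smaller than the change in its transcript.

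The table has 24351 probe sets. Of these, 2903 are control probe sets, which were left out of all gene counts, and 21448 are transcript probe sets. The platform annotation names 1 gene for 17709 of the transcript probe sets, several genes for 0 and none for 3739. All 17709 Entrez gene IDs matched the table of current human symbols (GRCh38.p14), and the update changed 0 symbols. A gene with several probe sets (20 of 17687 genes) took the one with the highest mean over both arrays. No genome build is named for the array, so no coordinates are given. Control probe sets were used to describe the arrays, with their kind read from their names. They comprised 612 negative controls, 2197 positive controls, 23 background probe sets, 4 hybridisation spike-ins, 4 labelling spike-ins and 63 ERCC spike-ins.

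There is 1 array per group, so no difference has a replicate check, no statistical test between the groups was run and no p-value is given. Percentiles among random lists describe these 2 arrays. Genes are not replicates. A difference is the converted value minus the pre-conversion value. Genes entered the count of 2-fold differences when the higher of their 2 values reached 5.01, the median over all transcript probe sets and both arrays (10166 genes). Lists of genes were described by the median difference of their measured members. That median was placed as a percentile among 10000 random lists of the same size, drawn from the same 20 bins of mean value. A list is said to stand apart when it lies outside the middle 95% of its random lists. Of 40 lists fixed, 39 had at least 3 measured members, and 1.95 would stand apart by chance if their members behaved as independent random genes. Members of a list may move together and some lists share genes, so that number is not a measure of how many would do so here. The number of arrays limits the precision. In place of replicate error, the spread between probe sets of 1 gene and the spread over olfactory receptor genes, which are not expected in these cells, were computed. Both cover error at the level of the probes and leave out the spread between cultures. A gene is called within the negative controls when neither of its values exceeds the 95th percentile of the negative control probe sets, which was 6.37 on the pre-conversion array and 7.07 on the converted array.

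The gene lists, the rule for named genes, the count of 2-fold differences and the alternatives were chosen before the data were examined, except where stated. The rule named the 10 genes with the largest difference each way among those that entered the count (leaving out small RNAs, unnamed transcripts, Y-linked genes and XIST), up to 4 members of each list with the largest difference, at most 3 of them in the direction of the list's median, and a fixed set of state markers. One of these, POU5F1, has no value under that name in the annotation used and is not analysed here. The alternatives were median centring, quantile normalization and loess of the difference on the mean value (span 0.4), the mean over probe sets, other filters on dim genes, thresholds of 1.5-fold and 3-fold, the mean in place of the median of a list, and unmatched random lists. A floor at each array's median of the negative controls was added after the data were seen. The functions were tested on simulated data made from the real means with a noise SD of 0.4. Of 100 genes simulated with a log2 difference of 2 each way, all drawn from brighter genes, 99 higher and 99 lower ones were recovered. Among 9652 genes, 124 unchanged ones were called. The simulated noise is smaller than the SD between probe sets of 1 gene (0.62) and over olfactory receptor genes (0.57). The count of unchanged genes called is therefore likely too low for these arrays. Of 1000 unshifted lists 45 stood apart, and of 20 shifted lists 20 did. Most of the 20 members of each shifted list came from the genes simulated higher by 2. That result was near certain, and it does not show whether smaller shifts or lists of dim genes would be found. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.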

Results

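Gene expression was profiled in 409B2 cells, an established human induced pluripotent stem cell line, before and after conversion from the primed state to a state described as naïve. Primed cells resemble the epiblast after implantation, and naïve cells the epiblast before it. The data consist of 1 microarray per state, each with log2 values for 21448 transcript probe sets. The median value was 5.06 on the pre-conversion array and 4.98 on the converted array. The interquartile range was 4.34 before and 3.68 after conversion. Of 17687 genes, 6920 (39.1%) exceeded the 95th percentile of the negative control probe sets on the pre-conversion array, and 5012 (28.3%) did so on the converted array. The cut-off was higher on the converted array (7.07 against 6.37), so the lower count need not mean fewer expressed genes. Across genes, the arrays correlated with a Pearson r of 0.94 and a Spearman rho of 0.93, where genes are not independent replicates.

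The question of the series was how the expression profile of the converted cells differs from that of the primed cells. The largest difference was that of PRRX1, a homeobox factor of mesenchymal cells, which was 2.45 before and 15.38 after conversion, a log2 difference of 12.93 (12.26 when the pre-conversion value is set to the median of the negative controls, 3.12). HPGD, the enzyme that degrades prostaglandins, was higher by 9.23 on the log2 scale. The other genes with the largest positive differences were the matricellular gene CCN1 (7.21), the transcription factor NFIX (7.11), IGFBP7 (6.77), DNMT3L (6.75), the splicing regulator MBNL1 (6.59), the glutamate receptor subunit GRIA3 (6.04), the matrix gene SPARC (5.84) and ZEB2 (5.57). On the lower side, the amino acid transporter SLC7A8 differed by -6.36 and the tight junction gene CLDN11 by -5.78. The mitochondrial creatine kinase CKMT1B differed by -5.67, a value that may be shared with its near-identical copy CKMT1A. The other genes with the largest negative differences were SPRY4 (-5.57), the WNT modulator SFRP2 (-5.12), FAM162A (-5.01), NLGN4X (-4.98), USP44 (-4.95), the histone gene H3C11 (-4.89) and WFDC2 (-4.74). These are differences between deposited values, and their size and order are uncertain where the lower value is not above the 95th percentile of the negative controls. This held for 7 of the 10 positive ones (all but CCN1, DNMT3L and SPARC), for 8 of the 10 negative ones (all but SFRP2 and H3C11), and for 88 of the 147 named genes that were at least 2-fold apart. CLDN11, CKMT1B and SPRY4 ended under the median of the negative controls, and with values floored there their differences were -5.66, -5.47 and -5.29. Probe sequences were not used here, so whether probes of the genes with the largest differences also read RNA of another species was not examined.

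Of 10166 genes that entered the count, 1117 were at least 2-fold higher and 2864 at least 2-fold lower on the converted array. At 8-fold, 89 were higher and 130 lower. This split depended on the scaling. The median difference was 0.24 among 5803 genes with a mean value under 4 and -0.61 among 531 genes with a mean of 12 or above. With that trend removed by loess, 1673 genes were higher and 1877 lower, and with quantile normalization 1682 and 1881, so that the share of higher genes among those past 2-fold was 28.1% as deposited, 47.1% with loess and 47.2% with quantile normalization. Without replicates, the error can be gauged only at the level of the probes. Probe sets of 1 gene differed from each other with an SD of 0.62 (42 probe sets of 20 genes). The 348 olfactory receptor genes, all within the negative controls, had a mean difference of 0.42 ± 0.57 (SD over genes), and 50 of them (14.4%) were at least 2-fold higher and 3 lower. A single 2-fold difference of a dim gene is therefore within what probes without expected signal showed.

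**Figure D1:**
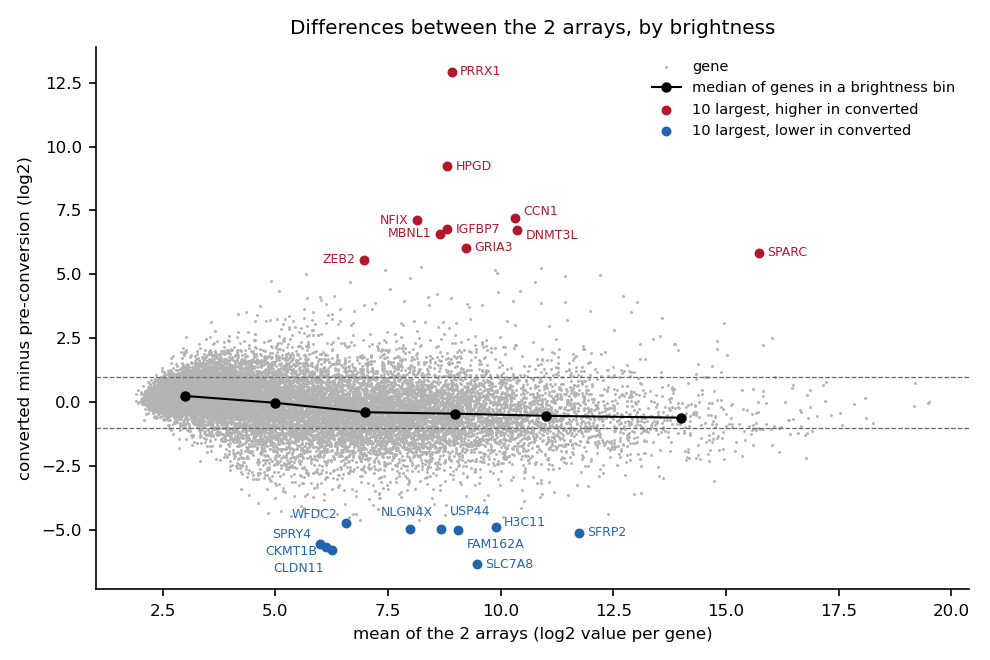
Difference between the arrays (converted minus pre-conversion, log2) against the mean of both arrays (log2) for each gene, with 1 array per group. Grey points are genes, the black line joins the medians of 6 brightness bins, which go from 0.24 to -0.61, dashed lines mark 2-fold, and the 10 largest differences each way are named.

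Genes used as markers of naïve pluripotency were higher on the converted array as a group. Of 28 measured markers, 12 were at least 2-fold higher, 3 at least 2-fold lower and 13 in between, and the median difference of 0.83 lay at the 100th percentile of matched random lists (middle 95% of those from -0.32 to 0.34). DNMT3L, a cofactor of the de novo DNA methyltransferases, was 108-fold higher, with a converted value of 13.75. DPPA3, a maternal factor of the early embryo, went from 8.04 to 10.52, and the meiotic gene HORMAD1 from 2.53 to 7.27. The T-box factor TBX3 was 3.81 before and 6.97 after conversion, within the negative controls. ESRRB (difference 1.18), KLF4 (1.06) and TFCP2L1 (1.02), transcription factors of the naïve network, were within the negative controls and under 2-fold after loess (0.93, 0.86 and 0.77). KLF17 (difference 0.57) and DPPA5 (-0.33) were within the negative controls too. SUSD2, a surface marker of naïve cells, was 4.71 and 5.01. The alkaline phosphatase gene ALPG was lower, at 9.09 before and 5.52 after. In all, 19 of the 28 markers were within the negative controls, and fibroblast markers were higher on the same array (median 0.80). Of the markers above the negative controls on at least 1 array, DNMT3L, HORMAD1, DPPA3 and FGF4 (1.80) were higher. ALPG, ALPP (-1.45), CBFA2T2 (-1.18), ZFP42 (-0.96) and TFAP2C (-0.09) had a negative difference. The positive median of the group therefore rests mostly on markers at background.

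Markers of primed pluripotency were lower as a group. Of 26 measured, 15 were at least 2-fold lower, 1 higher and 10 in between, with a median difference of -1.23 (0.01th percentile, middle 95% of matched lists from -0.81 to 0.13). SFRP2, NLGN4X and USP44 had the largest differences, given above. DNMT3B, a de novo DNA methyltransferase, was 15.78 before and 13.46 after, a 4.99-fold lower value. OTX2, a factor of the primed epiblast, differed by -1.26 and the surface marker CD24 by -1.19. Both were under 2-fold after loess, at -0.68 and -0.53. ZIC2 was 5.41 and 5.79, within the negative controls, and HMGA2 was higher by 1.44, also within them.

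Genes of the core pluripotency network did not stand apart as a group. Of 14 measured, 5 were at least 2-fold lower, 2 higher and 7 in between (median -0.72, 15.5th percentile, with a mean of -0.11). After loess 2 were lower and 3 higher, and with quantile normalization 4 and 3. NANOG was 12.79 before and 12.82 after, and 0.65 higher after loess. SOX2 went from 12.74 to 9.01, a 13.2-fold lower value, and the RNA-binding protein LIN28A from 15.46 to 13.90 (-0.90 after loess). NODAL, the ligand of the pathway that maintains the epiblast, was 8.28 before and 13.52 after, and the related ligand GDF3 10.62 and 14.79. Among 10 genes of the DNA methylation machinery, 4 were at least 2-fold lower and 1, DNMT3L, higher (26.9th percentile). UHRF1, which recruits the maintenance methyltransferase, differed by -1.84 and TET2 by -1.25. Of 3 measured transcripts associated with the retroviral element HERVH, HHLA1 differed by -2.70, ABHD12B by -0.30 and SCGB3A2 by 1.83 (60.2nd percentile).

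**Figure D2:**
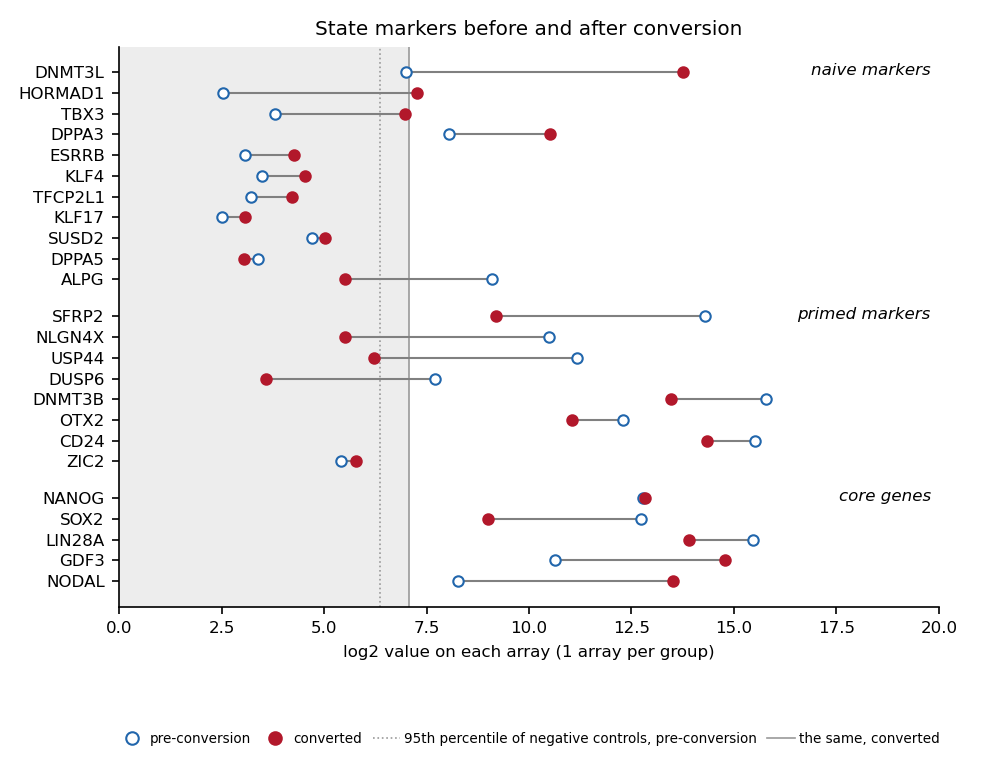
Log2 value of state markers on the pre-conversion array (open blue circles) and the converted array (filled red circles), 1 array per group. Vertical lines mark the 95th percentile of the negative control probe sets (6.37 dotted, 7.07 solid, shaded to its left), DNMT3L and DPPA3 end to the right of it, and KLF17, DPPA5, SUSD2, KLF4, ESRRB, TFCP2L1 and ZIC2 lie to its left on both arrays.

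Feedback and target genes of FGF and ERK signalling were lower on the converted array as a group. Of 19 measured, 10 were at least 2-fold lower, 1 higher and 8 in between (median -1.05, 0.62nd percentile). SPRY4, a feedback inhibitor of the pathway, was 8.78 before and 3.21 after. The ERK phosphatase gene DUSP6 was 7.72 and 3.57, and the ETS factor ETV5 had a converted value of 3.55. These 3 converted values were at background (median of the negative controls 3.49), so the size of these differences is uncertain. DUSP4 went the other way by 1.09, within the negative controls. Targets and components of NODAL and TGF-beta signalling were higher as a group. Of 10 measured, 5 were at least 2-fold higher and 1 lower (median 1.03, 99.96th percentile). Besides NODAL, LEFTY2, a feedback antagonist of NODAL, was higher by 3.84 and CYP26A1, which degrades retinoic acid, by 3.63. TGIF1 differed by -1.17, and by -0.54 after loess.

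WNT targets and LIF and STAT3 genes did not stand apart. Of 14 WNT targets, 3 were higher and 2 lower by 2-fold (89.7th percentile), with differences of 3.16 for TBXT, 1.29 for AXIN2, -2.33 for DKK1 and -1.90 for LEF1. Of 11 LIF and STAT3 genes, 2 were higher and 1 lower (58.7th percentile). The LIF co-receptor gene IL6ST was higher by 2.36, and STAT3 itself differed by -2.40.

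Markers of fibroblasts and of mesenchymal cells were higher on the converted array. Of 14 fibroblast markers, 6 were at least 2-fold higher and 1 lower (median 0.80, 99.9th percentile), and 11 of the 14 were within the negative controls. The collagen gene COL1A2 went from 9.72 to 14.69 and FAP from 3.22 to 6.39, beside PRRX1, while S100A4 was lower (6.35 and 4.45). Of 12 mesenchymal genes, 5 were higher and 1 lower (median 0.88, 99.9th percentile). After loess 9 were higher and 1 lower, and with quantile normalization 8 and 1. SPARC was 12.81 before and 18.65 after, ZEB2 4.18 and 9.74, and ZEB1 4.81 and 6.68, while SNAI1 differed by -1.93. HOX genes, which pattern the body axis, were also higher. All 15 measured had a positive difference as deposited and 7 were at least 2-fold higher (99.3rd percentile), with HOXC8 at 4.85 and 10.02, HOXC10 at 2.92 and 7.27, and HOXD8 at 3.64 and 6.99, although 13 of the 15 were within the negative controls. Of 15 epithelial genes, 5 were lower and 3 higher (median -0.82, 8.13th percentile). With dim genes left out the median was 0.07 (95.5th percentile), and among unmatched random lists the list stood apart on the lower side (0.68th). The claudin genes CLDN7 and CLDN6 differed by -1.78 and -1.59, RAB25 by -1.43 and MARVELD3 by 1.41.

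Markers of embryonic and extraembryonic lineages did not stand apart. Among 13 genes of mesoderm and primitive streak, 2 were higher and 2 lower by 2-fold (91.3rd percentile). With loess 4 were higher and 2 lower (96.3rd percentile), and with quantile normalization 4 and 2 as well (97.0th). TBXT, the primitive streak factor brachyury, differed by 3.16 and FGF8 by 2.32, while SNAI1 differed by -1.93 and TBX6 by -1.43. Of 17 trophoblast markers, 3 were higher and 2 lower (83.0th percentile), with HAND1 higher by 1.88 and TEAD4 at -1.38, or -0.98 after loess. With loess 2 trophoblast markers were higher and 0 lower (96.7th percentile), and with quantile normalization 2 and 0 as well (97.3rd). The 10 amnion markers lay at the 79.4th percentile, the 14 endoderm and hypoblast markers at the 36.6th, the 12 neural markers at the 68.1st, the 12 primordial germ cell markers at the 65.9th and the 15 genes of the 8-cell stage at the 75.4th. For neural and germ cell markers the mean had the opposite sign of the median (-0.04 against 0.19, and -0.27 against 0.11). Most of these markers were within the negative controls, 14 of 17 for trophoblast, 9 of 10 for amnion, 10 of 14 for endoderm, 9 of 12 for neural cells, 10 of 12 for germ cells and 13 of 15 for the 8-cell stage. Among single genes, the surface protein PDPN differed by -3.17, the germ cell gene DAZL by -3.02 (-2.65 with the floor at the negative controls, and within them on both arrays), NCAM1 by -2.80 and LAMA1 by -1.39 (-0.97 after loess). Germline genes silenced by promoter methylation reached the 97.4th percentile (4 of 17 higher, 1 lower), with PIWIL1 higher by 1.88 beside HORMAD1, which is also among the naïve markers. Of the 17, 15 were within the negative controls, PIWIL1 among them. This list stood apart with the mean of the members (99.78th percentile).

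Genes of glycolysis, of the hypoxia response, of the ribosome and of histones were lower beyond matched genes of like brightness. Of 20 glycolysis genes, 10 were at least 2-fold lower and 0 higher (median -1.05, 1.96th percentile), and after loess 8 lower and 1 higher (median -0.49, 2.02nd percentile). The glucose transporter gene SLC2A1 was 14.76 before and 11.16 after, ALDOC 10.37 and 6.94, and PKM 15.10 and 12.12, while LDHB was higher by 0.78. With dim genes left out, all 20 stayed in with the same median, but against random lists without dim genes that median lay at the 2.59th percentile and did not stand apart. Of 14 hypoxia genes, 8 were lower and 2 higher (median -1.57, 0.03rd percentile), with differences of -2.96 for DDIT4, -2.67 for KDM3A and 2.27 for ANKRD37. NDRG1, within the negative controls, differed by -2.76, or by -2.52 with the floor. Of 54 ribosomal protein genes, 30 were at least 2-fold lower and 0 higher (median -1.12 against -0.51 in matched lists, and -0.51 against 0.03 after loess, where 12 were lower and 1 higher), among them RPS29 (-2.88), RPS16 (-2.23) and RPS19 (-2.17). Of 64 histone genes, 37 were lower and 2 higher (median -1.17 against -0.25 in matched lists, and 22 lower and 0 higher after loess), among them H3C11 (-4.89), H3C1 (-2.77) and H1-10 (-2.87, or -2.56 with the floor at the negative controls, and within them). The list was meant for replication-dependent histones but also holds members that are not of that class, such as H1-10 and H1-8. Of the 64 histone genes, 23 were within the negative controls. Histone and ribosomal protein genes have near-identical copies, so single values are uncertain. Both families lay below all 10000 of their random lists.

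Nuclear genes of oxidative phosphorylation had a median difference of -0.95 and lay at the 3.71st percentile, inside the range of matched lists, with 12 of 24 at least 2-fold lower and 1 higher. After loess 7 were lower, and with quantile normalization 6. The list stood apart on the lower side with the mean of the members (1.26th percentile) and among unmatched random lists (0.02nd). NDUFB8 differed by -2.47, CYC1 by -2.39, COX7C by -2.23 and NDUFA9 by 1.94. Cell cycle genes lay at the 13.2nd percentile (7 of 20 lower, 1 higher, TOP2A -2.23 and AURKB -1.72). With loess, and also with quantile normalization, 3 of them were lower and 2 higher. The p53 targets lay at the 13.9th percentile (5 of 13 lower, 2 higher). Among the p53 targets, the cell cycle inhibitor CDKN1A went from 6.68 to 3.48 and BAX from 11.03 to 8.65, while TIGAR was higher by 2.43. Genes of serine and one-carbon metabolism lay at the 37.6th percentile, with PHGDH at -2.67 and SHMT2 at -2.38. Cholesterol synthesis lay at the 40.7th, with DHCR7 at -2.26 and FDPS at -2.22. The unfolded protein and amino acid stress genes lay at the 80.0th percentile with members on both sides and a mean of 0.06 against a median of -0.05, XBP1 at 2.23, DNAJB9 at 2.03, ATF4 at -2.19 and CHAC1 at -1.97. Heat shock genes lay at the 66.3rd percentile and 11 housekeeping genes at the 36.3rd. The median of the housekeeping genes was -0.63 as deposited and 0.03 after loess, and B2M, the light chain of MHC class I, was the member with the largest difference (9.56 and 5.96).

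**Figure D3:**
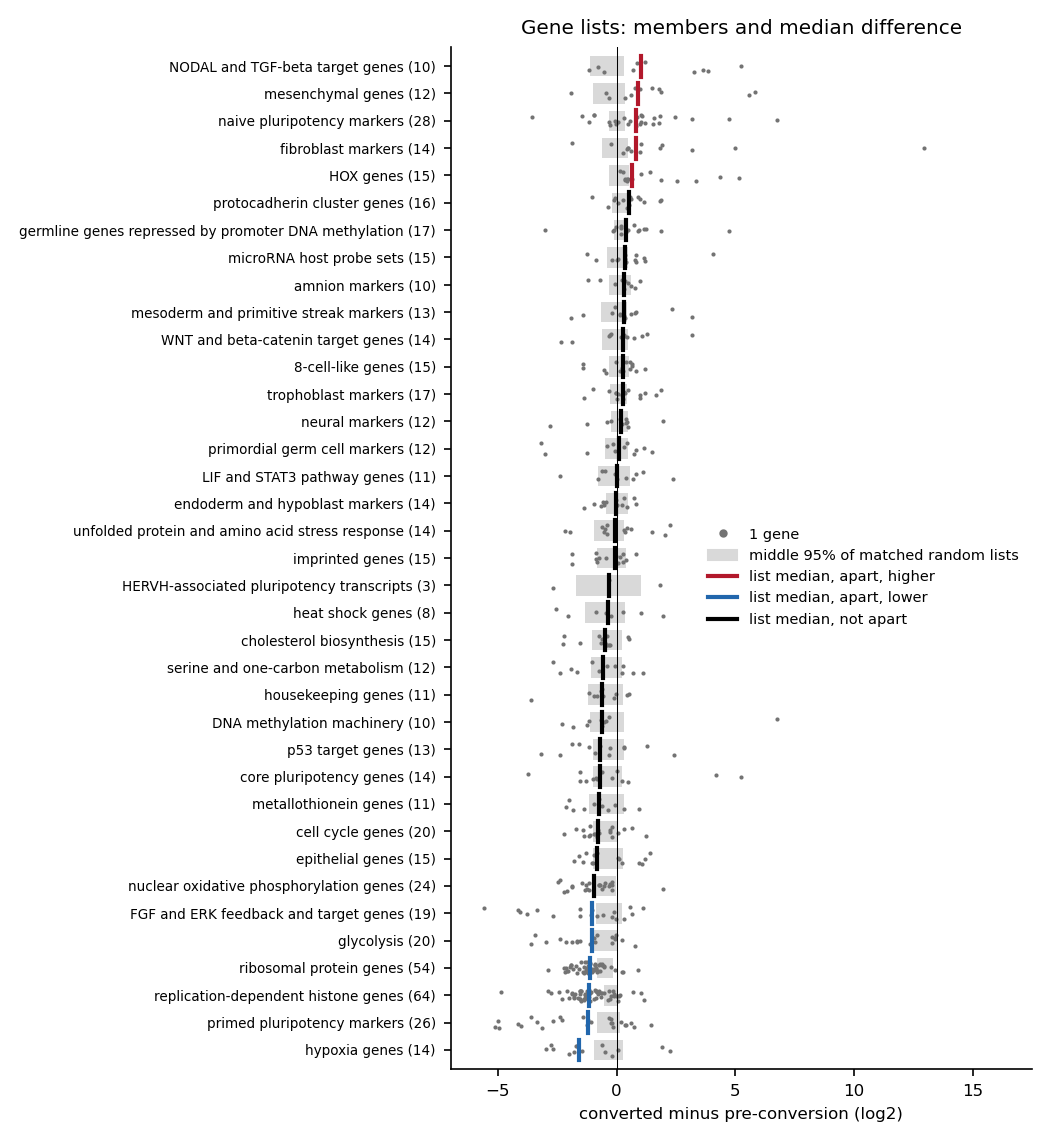
Log2 difference (converted minus pre-conversion) of the measured members of each gene list (grey points, number in brackets) with the list's median (vertical bar) and the middle 95% of 10000 matched random lists (grey box). Medians of 5 of the lists shown lie above their box (red) and 6 below (blue), and the centre of the box lies below 0 for lists of bright genes.

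Of the remaining families, imprinted genes lay at the 65.1st percentile (0 of 15 higher, 2 lower, NNAT at -1.90 and ZDBF2 at -1.87), metallothionein genes at the 21.6th (4 of 11 lower, MT1F at -2.14, with near-identical copies), clustered protocadherin genes at the 96.1st (3 of 16 higher, 1 lower), microRNA and microRNA host gene probe sets at the 92.7th (3 of 15 higher, 1 lower, MIR22HG higher by 4.08) and 482 ZNF zinc finger genes at the 86.6th (56 higher, 73 lower as deposited, but 75 and 55 with median centring, 74 and 50 with quantile normalization and 74 and 53 with loess). The ZNF list stood apart on the higher side with dim genes left out (99.25th percentile) and with the mean of the members (99.18th). Among the ZNF genes, ZNF365 was higher by 3.86, ZNF34 by 3.05 and ZNF503 by 2.99, and ZNF511 differed by -2.44. Olfactory receptor genes stood apart on the higher side (median 0.36 against 0.22 in matched lists), with OR10AG1 (2.38) and OR2T2 (2.32) the highest and OR5H14 (-1.29) the lowest, all within the negative controls. After loess 30 in place of 50 were at least 2-fold higher. Both measured small nucleolar RNA genes were lower by less than 2-fold, too few for a percentile. In all, 6 lists stood apart on the higher side and 6 on the lower side, of 39.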

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

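The tests of explanations below were chosen after the results were seen, except that of S-phase genes, whose values as a set had not been looked at. Values outside the gene comparison carried signal. The 4 hybridisation spike-ins, bacterial and phage transcripts added after labelling, were higher on the converted array by a mean of 1.12 on the log2 scale (from 0.79 to 1.39, SD 0.27 over probe sets). The 4 labelling spike-ins were higher by 1.03, and the 63 ERCC probe sets by 0.64, all 63 in that direction. Whether ERCC transcripts were added is not stated, and negative controls were higher by a mean of 0.28. Among 1640 transcript probe sets without a gene name that entered the count, 226 were at least 2-fold higher and 426 lower.

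Bright genes were lower and dim genes higher on the converted array. The median difference of 0.24 among genes with a mean value under 4 was also that of the negative controls (0.24). The rise of dim genes was therefore no larger than that of probes without expected signal. A candidate explanation of the trend is that the converted array carried less labelled sample signal before the authors scaled it. Spikes of fixed amount would then stand above transcripts of like brightness. The hybridisation spike-ins did so by 1.64 (spike-ins 1.12, transcripts -0.52). Both values had been seen before the explanation was set out and rest on 1 pair of arrays, so they leave it open. The labelling spike-ins were higher by 1.03 too, but were not compared with transcripts of like brightness. At which step sample signal may have been lost was therefore not tested. A difference between the cell states themselves, which the design names, stays open and untested.

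Fibroblast, mesenchymal and HOX genes were higher on the converted array. A scaling trend with brightness is argued against for the fibroblast list, which lay at the 99.94th percentile after loess. Its random lists were matched on brightness, so loess adds little beyond the percentile as deposited (99.86). Other forms of scaling were not tested. The HOX list, at the 97.7th after loess (median 0.43), was barely outside the range of its random lists and stays open. Human fibroblasts in the converted culture, as the whole cause, would raise abundant matrix genes together. COL1A1, COL6A3, DCN, LUM, POSTN and FBN1 had a median difference of 0.54 (SD 0.57 over 6 genes) against 4.97 for COL1A2, with DCN at 3.99 and COL1A1 at 9.23 on the converted array. Of the 6, LUM (1.84) and COL1A1 (1.03) were at least 2-fold higher and the rest were not. These genes and the comparison with COL1A2 were chosen after their values were seen, so they do not decide it. RNA of feeder cells of another species, read only by probes in conserved sequence, may account for the split between the 6 of 14 fibroblast markers that were at least 2-fold higher and the rest, and for other large differences such as that of MBNL1, but feeder cells are not named in the sources used here and probe sequences were not used here, so it cannot be told apart from a change in the converted cells themselves. That change, which the design names, remains open and untested.

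Genes of the histone list were lower. A scaling trend with brightness does not account for the whole of it, since after loess the list still had a median of -0.74. Its percentile was 0 as deposited and after loess. Random lists were matched on brightness in both cases, so loess adds little to that percentile. Fewer cells in S phase may contribute. The 9 S-phase genes of the cell cycle list had a median of -0.81 and lay at the 17.2nd percentile of matched lists (random median -0.45, SD 0.41), which decides neither way. A difference between the cell states, which the design names, stays open and untested.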

How the results depend on the processing

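No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. The use of a first gene symbol was not run, since no probe set had several. The counts of genes at least 2-fold higher and lower (1117 and 2864) became 1682 and 1881 with quantile normalization, 1673 and 1877 with loess, 1787 and 3062 with no filter on dim genes, 518 and 1811 with the 75th percentile filter, 483 and 1306 at 3-fold, and 1893 and 4336 at 1.5-fold. The other settings stayed within 1.5 times. In the settings run, 0 genes past the threshold changed direction, and loess shared 1089 of the higher and 1851 of the lower genes. Median centring moved the median difference of all genes from -0.03 to 0.12, and the floor at the negative controls, added after the data were seen, moved it to 0.11. The floors of the arrays differ by 0.36, so a list whose middle gene lies under both floors takes that value by construction, and its percentile with the floor, as for olfactory receptors and germline genes, shows nothing. Of the 8 alternatives run for the lists, median centring shifts all differences by the same constant, so it could not change a percentile. The mean over probe sets alters only the 20 genes with several probe sets, so it could change percentiles little. A list that stood apart in all 8 was therefore tested mainly by the remaining alternatives. Median differences of the primed list were -0.84 with quantile normalization, -0.80 with loess and -1.66 as a mean of the members, and it stood apart in all 8 alternatives. The naïve list was 0.60 with the floor and 1.01 without dim genes, and stood apart in all 8. The core list was -0.15, -0.078 and -0.11 with quantile normalization, loess and the mean, and stood apart only with unmatched random lists (1.51st percentile). The fibroblast, mesenchymal, NODAL, HOX, FGF and ERK, hypoxia, ribosomal and histone lists kept their side in all 8 alternatives, with values from 0.80 to 1.93, 0.88 to 1.38, 1.03 to 1.62, 0.43 to 1.88, -1.47 to -0.62, -1.57 to -1.01, -1.15 to -0.51 and -1.28 to -0.74. Glycolysis did not stand apart against random lists without dim genes (2.59th percentile, same median). Lists that stood apart only in an alternative were germline genes, oxidative phosphorylation, ZNF and microRNA genes with the mean of the members, ZNF genes without dim genes, protocadherins with the floor, and with unmatched random lists protocadherins and the lists added on the lower side. Unmatched random lists put 12 lists in place of 6 on the lower side, since random lists then ignore the trend with brightness. The SD over olfactory receptor genes was 0.998 among the 18 at or above the median, in place of 0.57. Of 147 named genes at least 2-fold apart, 0 changed sign and 16 came under 2-fold in at least 1 alternative, 13 of them with loess. Apart from the other thresholds, filters and random lists, whose construction sets the change, the cause was not tested. Signal over background limits markers within the negative controls.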

Other observations

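The tests in this part used lists added after the largest differences were seen, when the values of their other members had not been looked at, and the genes named here were chosen after their values were seen. Genes of smooth muscle and of the actin cytoskeleton driven by the factor SRF were higher on the converted array. Of 14 measured, 8 were at least 2-fold higher and 0 lower (median 1.86), but 4 of the 8 (ACTA2, ACTC1, CALD1 and CSRP1) prompted the list. Of the 10 others, 4 were at least 2-fold higher and 0 lower, and they had a median of 0.84 and lay at the 99.95th percentile of matched random lists, and at the 100th after loess. Among them, the calponin-related gene TAGLN went from 9.86 to 13.09, ACTG2 from 5.37 to 7.68 and CNN1 from 7.89 to 9.35, and the myosin light chain gene MYL9 was higher by 2.26. The remaining 6 of the 10 were under 2-fold. Of these, SMTN was 8.44 and 8.51, VCL 12.63 and 12.41, and MYH11 and LMOD1 differed by 0.39 and 0.22. None of the list is in a list fixed before, and 10 of 14 exceeded the negative controls on the pre-conversion array already. The hypothesis that contractile genes as a class were higher on the converted array met its prediction on the members not seen before, within 1 pair of arrays. They may share a cause with the fibroblast and mesenchymal genes, which was not tested.

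CCN1, a target of the YAP and TEAD factors, led to a second list. The 16 members not seen before lay at the 75.5th percentile (median 0.01), and at the 93.5th after loess (median 0.36), so the hypothesis that YAP and TEAD targets were higher as a class was left open. ANKRD1 was higher by 2.75 with both values within the negative controls, CCN2 differed by 0.00 (7.72 on both arrays), and AXL differed by -1.13.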
